A study of Homo sapiens with 5 samples.

How the data were processed

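NRF2 ChIP-seq was carried out in BEAS-2B cells, with 2 samples treated with sulforaphane, 2 with vehicle and 1 vehicle sample precipitated with IgG, 5 in all. Samples were grouped by treatment and antibody as the labels give them. Per the labels' protocols, complexes were recovered from sonicated nuclei with a rabbit monoclonal antibody against NRF2, libraries were amplified by PCR, fragments were selected by size on a gel, and sequencing was done on the Genome Analyzer. Nothing in the labels says whether samples of a group came from separate cultures. Per the submitters' processing notes, CASAVA 1.4, BWA and MACS2 were used, with the genome build hg19.

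The deposited files were 2 peak lists, 1 for each treatment, each called with MACS 2.1.0.20140616 per the file headers. Each header names 1 treatment alignment and 1 control whose name carries both the words input and IgG, and it is not given in the sources used here whether the samples of a treatment were pooled before calling. Per the file headers, tags were 36 bp long, at most 1 tag was kept per position, the effective genome size was set to 2700000000 bp, the q cutoff was 0.05, and the fragment length was estimated as 153 bp for SFN and 154 bp for vehicle. The headers give a redundant share of 0.68 for SFN tags, 0.87 for vehicle tags and 0.17 for control tags. Of 23090154 SFN tags 7448599 were kept, of 11377334 vehicle tags 1459665, and of 33810302 control tags 28125771. The kept control tags were 3.78 times the kept SFN tags and 19.3 times the kept vehicle tags. The limit on tags per position removes amplified copies and also caps the height of true peaks, and the differing share removed means that the lists differ in usable depth by more than in tags sequenced.

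Each peak has a position, a signal, which is the tag pileup at the summit as the authors' caller gave it, a fold over the local control, which is a ratio the authors deposited, and −log10 p and −log10 q values, also as deposited. The fold and pileup were used to describe, rank and filter peaks within a list and were not tested between lists. The caller's fold is the pileup plus 1 over the local control level plus 1, so the local control level was computed back from the deposited fold and pileup. With this level, the deposited −log10 p was obtained again to within 0.0001 for all 1925 SFN and all 2199 vehicle peaks, with a Poisson upper tail. The control level is given as a multiple of the genome average expected at the list's depth, which was 0.422 tags for SFN and 0.0833 for vehicle. It is the caller's local value and not a count of control tags at the peak. Its lowest value was 1.00 in both lists, so places where the control lay below the genome average cannot be told apart. The limit of 3 for a low control level was chosen after the data were seen.

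A peak was shared when it overlapped a peak of the other list by at least 1 bp. Overlap was tested against 1000 placements of the vehicle peaks at random positions of the same chromosome, between the lowest and highest position seen in either list, and unmappable gaps were not left out. The top and bottom 25% of a list by fold were compared with Fisher's exact test, two-sided, as were shared and unshared peaks. The 6 tests of the report in its reported settings were adjusted together by the Benjamini-Hochberg method. The tests in alternative settings, of grouping and of callable peaks were not adjusted. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error alone. Peaks at most 10 kb apart were joined into regions. No test across replicates, no analysis without each replicate and no pairing could be made, since no list holds values per sample. The IgG sample was not analysed on its own here.

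Peaks were named by a rule fixed before the data were examined: the 15 highest by fold among SFN peaks that overlap no vehicle peak, the 10 highest among shared SFN peaks and the 10 highest among vehicle peaks that overlap no SFN peak, given by position where no annotation of the build is used. Regions and groups of peaks named besides these were chosen after their values were seen. A genome sequence and a gene annotation of hg19 were not used here. For that reason 5 planned results were not run: the shares of peaks with the core antioxidant response element, with the AP-1 site and with the reversed element, the share near transcription starts, and the peaks near genes of 11 gene lists. NRF2 is known to act at regulatory elements of genes such as NQO1, HMOX1 and TXNRD1, and which peaks lie beside which genes was not determined here.

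To set depth against binding, the height that a peak of one list would have in the other library at equal occupancy was taken as the lower 95% Poisson limit of its height scaled by the ratio of kept tags. A peak was taken as callable when the chance of reaching the weakest p of the other list was 0.95 or more, and 0.8, and the height itself, were tried as alternatives. The call probabilities were also summed over a set to give the number expected in the other list. This assumes equal efficiency of the precipitations. Tags placed at random over the effective genome size were simulated 20 times as independent tags at the depth of each library, at 1.5 times that density, and as fragments that each give 2 tags at the same place. Alternatives tried were a q of 1e-05 or less, chromosomes 1 to 22 and X, the top 500 peaks of each list, an overlap of 50% of the shorter peak, summits at most 100 bp apart, the ranking by −log10 p, other limits of the control level (1.5 and 5) and joined regions. Before use, the overlap count was tested on simulated data for the comparison of SFN with vehicle, with 1924 and 2199 peaks placed at random, and 200 of 200 planted overlaps were recovered. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.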

Results

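NRF2 is a transcription factor that drives the cellular response to electrophiles and oxidants, and sulforaphane (SFN), an isothiocyanate from cruciferous vegetables, is a known activator of it. NRF2-bound DNA was recovered by chromatin immunoprecipitation and sequenced (ChIP-seq) from BEAS-2B cells, an established line of human bronchial epithelial cells. Cells had been treated for 5 h with 10 µM D,L-sulforaphane (2 samples) or with 0.1% DMSO as vehicle (2 samples), and 1 vehicle sample was precipitated with IgG. The values analysed here were 2 peak lists, 1 per treatment, so no value per sample and no spread between replicates could be given, and every comparison below is between 2 lists and not between replicated conditions. Per the file headers, the SFN list rested on 23090154 tags, of which 7448599 (32.3%) were kept after the limit of 1 tag per position. The vehicle list rested on 11377334 tags, of which 1459665 (12.8%) were kept. The SFN list therefore had 5.10 times as many usable tags as the vehicle list. Both lists were called against the same control of 28125771 kept tags.

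The first comparison asked where NRF2 peaks were called in each treatment. The SFN list held 1925 peaks and the vehicle list 2199, in hg19 coordinates. Peaks of the SFN list were built from more tags, with a median of 26 tags at the summit against 6 in the vehicle list, and a median width of 234 bp against 158 bp. The median of the caller's fold over the local control, which is the authors' value for each peak, was 5.12 in the SFN list and 5.44 in the vehicle list, and 156 SFN peaks and 133 vehicle peaks had a fold of 10 or more. With only peaks at a q of 1e-05 or less, the order of the list lengths turned, with 1485 SFN peaks and 1082 vehicle peaks. Peak number and tag height both depend on depth, which differed between the lists, so neither was tested between the treatments.

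The peaks of both lists differed in the local control level computed from the caller's fold. A part of each list lay in crowded regions, mostly where the control was high as well. In the SFN list, 846 peaks (43.9%) lay in 42 regions of 5 or more peaks spaced at most 10 kb apart, and in the vehicle list 704 peaks (32.0%) lay in 34 such regions. The region with most peaks was chr4:49093815-49158634, with 91 SFN peaks, of which 88 overlapped a vehicle peak, and the vehicle list had 101 peaks in nearly the same span, at chr4:49093301-49158543. The median control level in that SFN region was 24.1 times the genome average. The regions next in size in the SFN list were chrY:58819353-58917658 with 90 peaks, all of them shared with the vehicle list, chr10:42355371-42409492 with 64 peaks (52 shared) and chrX:61682130-61727933 with 50 peaks (29 shared). Their median control levels were 33.9, 31.4 and 17.6 times the genome average. Another part stood mostly alone at a control level under 3 times the genome average, a limit chosen after the data were seen. There were 725 such peaks in the SFN list, of which 674 (93.0%) had no other peak within 10 kb, and 1206 in the vehicle list, of which 1121 (93.0%) had none. Not every peak belonged to these parts: of the 1200 SFN peaks at a control level of 3 or more, 837 lay in the crowded regions and 220 stood alone, and of the 993 such vehicle peaks it was 692 and 175.

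**Figure D1:**
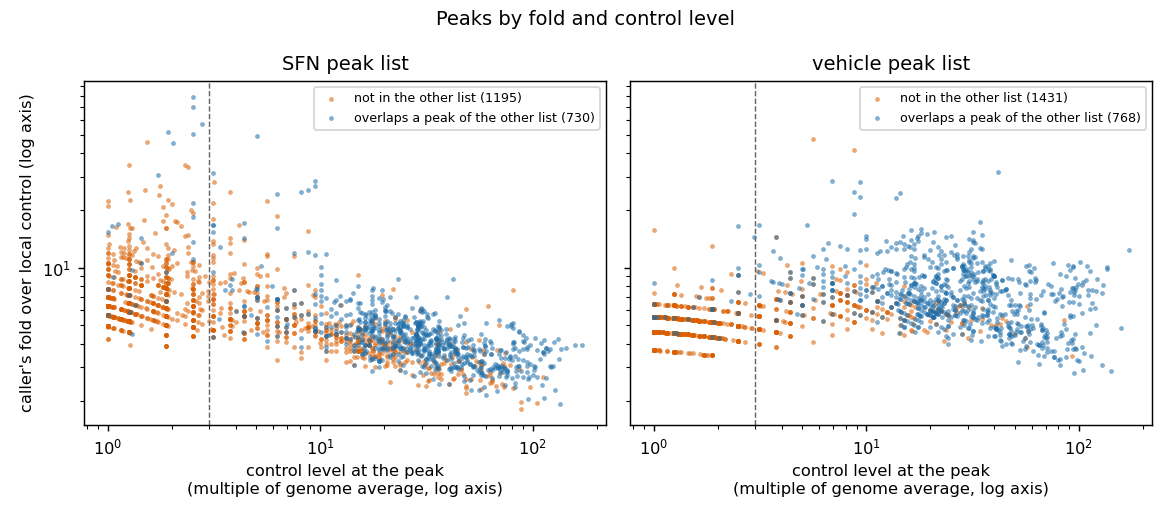
Each point is a peak of the SFN list (left) or the vehicle list (right), placed by the control level at the peak as a multiple of the genome average (log axis) and by the caller's fold over the local control (log axis), with the dashed line at a control level of 3. Blue points, 730 in the SFN list and 768 in the vehicle list, overlap a peak of the other list and lie mostly to the right of the line, and orange points, 1195 and 1431, do not overlap.

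The second comparison asked which NRF2 peaks the treatments shared. Of the SFN peaks, 730 of 1925 (37.9%, exact 95% interval 35.7 to 40.1) overlapped a vehicle peak by at least 1 bp, and 768 of 2199 vehicle peaks (34.9%, 32.9 to 37.0) overlapped an SFN peak. Random placement of the vehicle peaks along the same chromosomes gave a mean of 1.52 overlapping SFN peaks and at most 12 in 1000 placements (one-sided permutation p = 0.001, the smallest these placements can give). Sharing rose with the control level. Of the SFN peaks, 27 of 725 (3.72%, 2.47 to 5.37) were shared at a control level under 3, 68 of 285 (23.9%, 19.0 to 29.2) from 3 to 10, 309 of 498 (62.0%, 57.6 to 66.3) from 10 to 30, and 326 of 417 (78.2%, 73.9 to 82.0) at 30 or more. In the vehicle list the shares were 28 of 1206 (2.32%, 1.55 to 3.34), 84 of 250 (33.6%, 27.8 to 39.8), 323 of 393 (82.2%, 78.0 to 85.8) and 333 of 350 (95.1%, 92.3 to 97.1). Peaks at a control level under 3 were 27 of the 730 shared and 698 of the 1195 unshared SFN peaks (Fisher's exact test, two-sided, p = 6.44e-153, Benjamini-Hochberg adjusted p = 1.93e-152 over 6 tests). In the vehicle list they were 28 of 768 and 1178 of 1431 (Fisher's exact test, p = 5.57e-317, adjusted p = 3.34e-316). Peaks within a crowded region are not independent of each other, so these tests and intervals cover counting error alone and describe the lists.

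**Figure D2:**
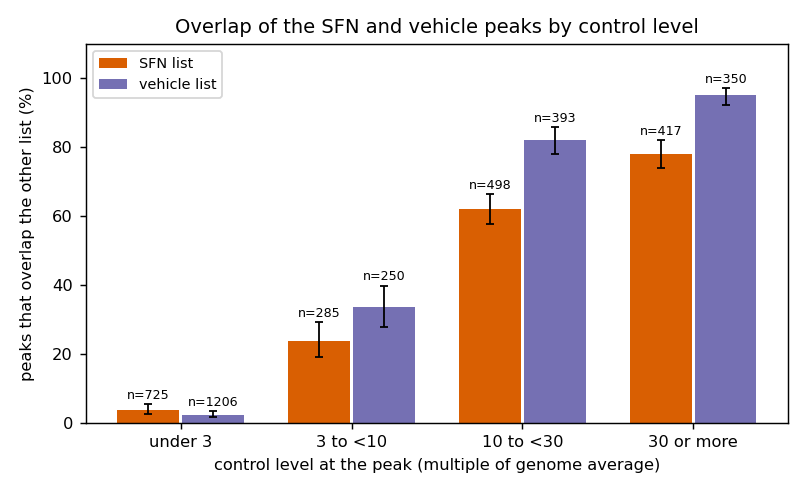
Bars give the percentage of peaks that overlap a peak of the other list, by the control level at the peak as a multiple of the genome average, for the SFN list (orange) and the vehicle list (purple), with exact 95% binomial intervals and the number of peaks above each bar. The share rises from 3.72% to 78.2% in the SFN list and from 2.32% to 95.1% in the vehicle list.

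Sharing was also compared between the ends of each list as ranked by the caller's fold. In the SFN list, 88 of the 481 peaks in the top 25% were shared (18.3%), against 306 of the 481 in the bottom 25% (Fisher's exact test, two-sided, p = 6.66e-48, adjusted p = 9.99e-48). In the vehicle list it was 450 of 549 in the top 25% (82.0%) against 90 of 549 in the bottom 25% (Fisher's exact test, p = 4.60e-113, adjusted p = 9.20e-113). The upper quartile of fold was 6.53 over all vehicle peaks, but 5.54 among those at a control level under 3. Few of these could thus enter the top 25%, and the vehicle comparison largely repeats the split by control level. It was not tried in other settings. The direction in the SFN list held for the ranking by fold over all peaks and turned in 3 other settings. Ranked by −log10 p, the top 25% were shared more often by 61.1 percentage points (Fisher's exact p = 1.33e-91), and among peaks at a control level under 3 in both lists they were shared more often by 9.39 points (p = 5.12e-05). With 1 peak per region, a setting chosen like the limit of 3 after the data were seen, the difference was 3.95 points in the same direction as these, with an exact p of 0.278.

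Most of the highest folds of the SFN list were at peaks with no other within 10 kb, and several of them had a small vehicle peak at the same place. The peak with the highest fold, chr16:88366742-88367282, had 162 tags at the summit and a fold of 79.2, and the vehicle peak there had 10 tags and a fold of 9.11. At chr17:15546128-15546627 there were 143 tags and a fold of 69.9 in the SFN list, and 12 tags and a fold of 10.3 in the vehicle list. The SFN peak at chr16:69760632-69761102 had 122 tags (fold 56.6) and its vehicle peak 7 tags (fold 6.71). The SFN peak at chr11:61739292-61739675 had 92 tags (fold 51.4) and its vehicle peak 5 tags (fold 5.17). At chr3:53304037-53304471 the tags were 103 and 11, at chr17:18625074-18625566 152 and 12, and at chrX:153770066-153770614 83 and 4. The shared peaks next in fold were chr12:95263-95838 (72 tags, 20 in the vehicle list), chr4:8305274-8305663 (52 and 7) and chr5:9903-11880 (141 and 53). All 10 stood alone within 10 kb in the SFN list, and 7 had a control level under 3. The peak chr5:9903-11880 belonged to a group at chromosome starts. In the SFN list 5 peaks on 5 chromosomes started below position 20000, with folds from 11.8 to 28.6, and all 5 were shared. The vehicle list also had 5 such peaks, all shared, with folds from 6.06 to 24.6. Whether the peaks at chromosome starts come from bound DNA or from background was not tested. The tags and folds of the 10 shared peaks are as called in lists of unequal depth, so their change between the lists was not tested.

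Among SFN peaks that overlapped no vehicle peak, the 15 with the highest fold had folds from 21.9 to 45.6 and from 31 to 75 tags, and 11 of them had a control level under 3. The highest was chr14:106208117-106208669 with 74 tags and a fold of 45.6. It was followed by chr8:62634443-62634759 (52 tags, fold 34.6), chr22:35767885-35768272 (67 tags, fold 34.5), chr12:104680146-104680898 (67 tags, fold 33.8) and chr17:48739112-48739479 (65 tags, fold 28.2). A second peak of this set lay near the one on chromosome 22, at chr22:35772878-35773294, with 46 tags and a fold of 26.9. Chromosome 12 also held chr12:104613145-104613462, with 41 tags and a fold of 25.7. The remaining members were chr4:6734331-6734698, chr2:29353233-29353499, chr14:106091318-106091598, chr5:57555615-57555983, chr3:14452202-14452515, chr7:43612141-43612449, chr17:19656311-19656659 and chr2:241327029-241327380. Their absence from the vehicle list is the absence of a call at 1459665 kept tags and not a measured absence of binding. Of the 15, 5 were callable at that depth as defined above, which assumes equal efficiency of the precipitations.

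Among vehicle peaks that overlapped no SFN peak, the 10 with the highest fold had folds from 9.96 to 47.7 and from 10 to 71 tags, and 3 had a control level under 3. The top places were held by 2 neighbouring peaks whose starts lay 3806 bp apart, chr16:222887-223674 with 69 tags and a fold of 47.7, and chr16:226693-227485 with 71 tags and a fold of 41.7. Their control levels were 5.61 and 8.73 times the genome average. Whether these peaks come from NRF2-bound DNA or from DNA of another source in the vehicle library was not tested, and this holds for the vehicle list as a whole. The folds of the other 8 were far lower, led by chr11:5246726-5246997 (16 tags, fold 15.7), chr3:195551127-195551776 (18 tags, fold 14.5) and chr1:53749381-53749944 (14 tags, fold 13.0). The remaining members were chrY:13648962-13649125, chr10:39151129-39151301, chrY:13865983-13866145, chr7:156931406-156931682 and chr12:53969194-53969364.

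At a control level under 3, the lists differed in the height of their peaks. The 725 SFN peaks had a median of 9 tags, 355 of them (49.0%) had 10 tags or more and 29 had 30 or more, and 115 had a fold of 10 or more. The 1206 vehicle peaks had a median of 5 tags, 1054 of them (87.4%) had from 3 to 5 tags, 10 had 10 or more and none reached 30 tags, and 4 had a fold of 10 or more. Height and fold both depend on depth, so these counts were not tested between the lists. In these sets 25 SFN peaks overlapped a vehicle peak of the same kind, against a mean of 0.118 and at most 2 in 1000 random placements (one-sided permutation p = 0.001, the smallest these placements can give; adjusted p = 0.001). Sharing was more frequent at the top of the SFN set. Of its 10 peaks with the highest fold 6 overlapped a vehicle peak, of the top 50 it was 14, and of all 725 it was 27. In these 27 the SFN peaks had a median of 22 tags and a median fold of 13.6, and the vehicle peaks at the same places a median of 6 tags, from 4 to 19.

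**Figure D3:**
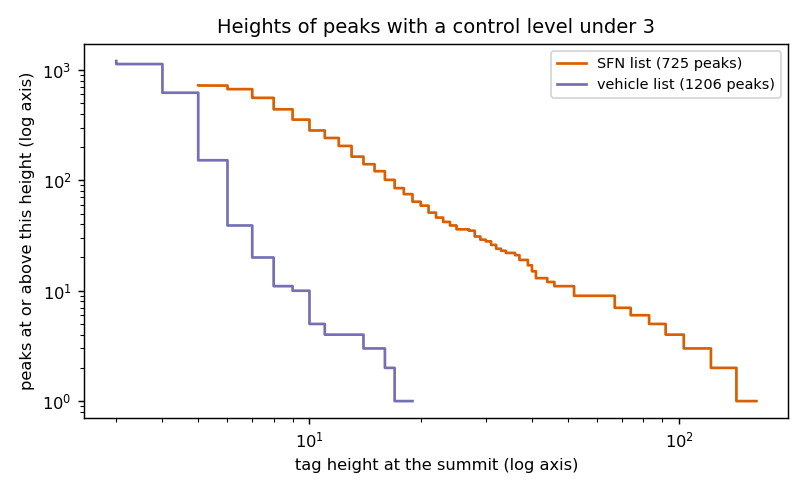
Lines give the number of peaks (log axis) whose summit is at or above a given tag height (log axis), for the 725 SFN peaks (orange) and the 1206 vehicle peaks (purple) with a control level under 3. The vehicle line ends at 19 tags and the SFN line at 162, with heights as called in lists of 7448599 and 1459665 kept tags.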

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

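The settings by control level and by joined regions, and the results on low-control peaks, were chosen after the data were seen; the other settings were fixed before. The SFN list of 1925 peaks had 725 at a control level under 3, 724 of them on chromosomes 1 to 22 and X, and 1012 regions after joining peaks within 10 kb. The vehicle list of 2199 peaks had 1206, 1189 and 1412, and 1082 at a q of 1e-05 or less. The 730 shared SFN peaks became 272 with the top 500 peaks of each list, 25 at a control level under 3 and 149 as joined regions, each from fewer peaks by construction. They stayed between 513 and 704 in 4 other settings, and the permutation p was 0.001 in all 7. The difference between the top and bottom 25% of the SFN list by fold was −45.3 percentage points and kept its sign in 5 of 8 settings. It turned to 61.1 with the ranking by −log10 p, to 9.39 at a control level under 3 and to 3.95 with 1 peak per region (Fisher's exact p = 0.278). SFN peaks at a control level of 3 or more had a lower median fold (4.25) than those under 3 (6.33) and were shared more often. The ranking by fold thus partly ordered the peaks by control level, and how far this made the turn was not tested. The 25 shared low-control peaks were 9 at a limit of 1.5, 45 at a limit of 5, 14 at a q of 1e-05 or less and 4 with the top 500 peaks, with a permutation p of 0.001 in each. The share of callable low-control SFN peaks missing from the vehicle list was 41.7% (exact 95% interval 15.2 to 72.3), 61.9% at a probability of 0.8 or from the height itself, and 72.7% with both, above that interval; the cause was not tested. Settings that need the genome sequence or gene annotation, such as repeats, motif windows and distances to genes, were not run. No paired analysis was possible because each treatment has 1 peak list and no values per sample. The 1459665 kept vehicle tags limit what can be said of peaks missing from the vehicle list.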

Other observations

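The comparisons by control level, the test of fragments counted at both ends, the numbers expected at equal occupancy and the tests of grouping were chosen after the results were seen. So were the comparison of callable peaks between control levels and the share of callable low-control vehicle peaks missing from the SFN list. The other tests of callable peaks at a probability of 0.95 and the test of chance stacks were set before their own results were seen. They used peaks picked by limits of the control level that were chosen after the data were seen.

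Isolated SFN peaks were seen on most chromosomes. Of the 725 SFN peaks with a control level under 3, 140 (19.3%) were higher than the highest stack of 14 tags in any simulation at the SFN depth, and 18 of these overlapped a vehicle peak. Chromosome 1 held 15 of them and chromosome 6 held 12, and chromosomes 13 and 19 held none. In the vehicle list, 5 of 1206 were higher than the highest simulated stack of 10 tags, and 3 of these overlapped an SFN peak. The SFN peaks above the stacks lay near one another more often than random placement gave, with 10 of 140 within 50 kb of another against a mean of 0.679 and at most 8 in 1000 placements (permutation p = 0.001, the smallest possible). They formed 5 pairs, at chr22:35767885-35773294, chr14:106091318-106110384, chr10:81077460-81081219, chr8:128863717-128867062 and chr6:34625188-34632356. Grouping was not specific to the SFN list, since 134 of the 1206 low-control vehicle peaks also had another within 50 kb, against a mean of 47.9 and at most 78 (permutation p = 0.001).

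The overlap of the lists lay mostly where the control was high. Of the shared peaks 96.3% in the SFN list and 96.4% in the vehicle list had a control level of 3 or more, against 41.6% and 17.7% of the unshared peaks. Background that also rises in the control is thus a candidate source of the shared peaks at a high control level, and repeated sequence there was not tested. At a control level under 3, 25 SFN peaks overlapped a vehicle peak of the same kind, against at most 2 in 1000 random placements, and at a limit of 1.5 it was 9. The placements took every position of a chromosome as equally likely, so they cannot exclude background shared by both lists at these places. NRF2 binding already present without sulforaphane may also underlie the 25 overlaps, and this stays a hypothesis that was not tested.

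Most low-control SFN peaks, 698 of 725, had no vehicle peak, in a list with fewer tags. The test set beforehand left depth undecided: of the 12 peaks with a call probability of 0.95 or more, 5 were missing (41.7%, exact 95% interval 15.2 to 72.3), between the 5% set for depth as the whole reason and the 50% set against it, and not distinguishable from 8 of 33 at a high control level (24.2%, Fisher's exact p = 0.285). In settings chosen afterwards it was 13 of 21 against 12 of 63 at a probability of 0.8 (Fisher's exact p = 5.62e-04), 13 of 21 against 12 of 65 from the height itself (p = 5.15e-04) and 32 of 44 against 28 of 149 with both (p = 6.41e-11). Equal occupancy, from the lower limit of each height and also chosen afterwards, would give 89.0 ± 7.12 (SD, counting error) of the 725. In the vehicle list 27 were called. For the 140 peaks above any simulated stack it was 59.2 ± 4.87, where 18 were called. At a high control level it was 256 ± 11.5 of 1200, where 703 were called, so the calculation fell short there. SFN peaks of few tags can be chance stacks. Independent tags at the SFN depth gave 5837 regions of 5 or more tags on average, but 0.05 of 10 or more. Fragments that each gave 2 tags produced 235 regions of 10 or more tags, and at most 14 tags. These simulated regions were not passed through the caller, so they do not count the stacks in the list. The 140 peaks above the stacks argue against fewer vehicle tags as their whole reason only under certain conditions. The precipitations must have been equally efficient, and the calculation must hold at a low control level. The peaks must also not be chance stacks at places denser than those simulated. A lower efficiency in the vehicle samples and a gain of binding with sulforaphane stay open and untested, since each treatment has 1 list.

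The low-control vehicle peaks of few tags were mostly missing from the SFN list, although that list had 5.10 times the tags. Independent tags stacked by chance gave at most 27 regions of 5 or more tags at 1.5 times the average density, against 385 vehicle peaks of that height at a control level under 1.5. Of the 1206 peaks, the SFN depth would call 125 (10.4%) with a probability of 0.95 or more from the lower limit of their height. It was 566 (46.9%) at a probability of 0.8, and all 1206 from the height itself. The test set beforehand foresaw under 50% if too few SFN tags were the reason, and the 10.4% met this. It cannot decide, since 1054 of the peaks had from 3 to 5 tags and thus low limits whatever the reason. In a comparison chosen afterwards, 109 of the 125 were missing (87.2%, 80.0 to 92.5). At a high control level it was 161 of 878 (18.3%, Fisher's exact p = 7.30e-53). The number expected at equal occupancy from the lower limit of each height, a measure chosen afterwards, was 868 ± 13.6 (SD, counting error) of the 1206, where 28 were called, against 740 called of 959 expected at a high control level. For the 5 peaks above any simulated stack, 5 were expected and 3 were called, so the shortfall rests on the lower peaks. It argues against too few SFN tags as the whole reason for these only if the precipitations were equally efficient. Fragments that each gave 2 tags at the same place produced 593 regions of 5 or more tags on average (541 to 637), within the range set for a match to the 385. Simulated regions, here and for independent tags, cover the whole effective genome and were not passed through the caller. The 385 are called peaks, so the counts are only roughly comparable. The match was also set for 6 or more tags, and it failed there. Such heights are even, so all of these regions had 6 or more tags, against 67 vehicle peaks. Of the 825 vehicle peaks at a control level under 1.5, 385 had odd heights. The even heights were fixed by placing both tags of a fragment at the same place. These values thus argue only against that setting as the whole source. Ends that overlap in part can give odd heights and were not simulated. The median width of the 1206 low-control vehicle peaks was the smallest width in the vehicle list. It equalled the fragment length that the caller estimated for vehicle. Whether this width tells the possible sources of these peaks apart was not tested. Both ends counted for all or part of the fragments and a loss of binding with sulforaphane stay open.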
